A study of Homo sapiens with 5 samples.

How the data were processed

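Single cells from human scalp hair follicles were measured in 5 libraries, 3 titled DS (Drop-seq, a droplet method with barcoded beads) and 2 titled 10X (a commercial droplet platform). The labels give no treatment and no other grouping, and they do not state whether the libraries came from separate donors. Per the labels, follicles were split into single cells with dispase and trypsin and enriched for live cells by fluorescence-activated cell sorting (FACS). The protocol text names the Drop-seq procedure for all libraries, including those titled 10X.

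The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. They were whole numbers in every table. The submitters' processing notes name HISAT2 and the GRCh38 genome without versions or roles, while gene names in the 10X tables carry an hg19 prefix; the counting program and the annotation are not given in the sources used here. Barcodes numbered 3000 in each DS table and 6000 in each 10X table. Genes are identified by symbol, as in the tables, which give no positions. Symbols were updated to current names, and 14047 names were found in the tables of both kinds.

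The total UMI count was 232077 in DS 1, 549171 in DS 2, 989924 in DS 3, 45376215 in 10X 1 and 10400085 in 10X 2. Barcodes with at least 300 detected genes and at most 20 percent of counts from mitochondrially encoded genes were kept as cells. Scrublet, as built into scanpy 1.11.5, called doublets per library, and these were removed: 21 in DS 1, 5 in DS 2, 2 in DS 3, 40 in 10X 1 and 7 in 10X 2. The 21 were 34.4% of the 61 cells of DS 1, where so few cells make the call unreliable. The remaining cells were 40, 250, 484, 3981 and 1081, in that order of libraries. They had median UMI counts of 768, 984.5, 1088, 9051 and 6292. Median detected genes, taken before doublets were removed, were 430, 542, 577, 2455 and 1945.5.

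Each library was clustered on its own in Python 3.11.15 (anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, sklearn 1.9.0, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 were used. Clustering was allowed to use only the 140 cell type markers of 20 classes and those genes on no gene list whose symbol has an even CRC32 checksum. The other genes were kept out, so that they could be compared between classes made without them. The exclusion does not remove genes that vary together with clustering genes, so a comparison of classes measures how far classes differ, not whether they exist.

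Clusters were named from the fixed markers. A class needed a marker score of at least 0.6 and at least 3 detected markers, where a detected marker was seen in 10 percent of the cells and in 3 cells. Among the suprabasal, differentiated, inner root sheath and shaft classes, a cluster whose runner-up scored at least 0.4 of the best was left unnamed as mixed. Clusters whose 10 leading genes held more markers of another class than of the best-scoring class did not get that name. Nor did clusters whose median UMI count was below that of the library divided by 3 and whose leading genes held none of the markers. Clusters still unnamed were compared with those 4 classes and called basal if the basal markers passed the same score. The score of 0.6 was set after the counts were opened. All class names mean cells like that type by these markers. Named clusters with low UMI counts were kept in their class.

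Counts were summed per library and class, since cells of a suspension are not replicates. A library entered a comparison with at least 20 cells on each side. In R 4.3.3, edgeR 4.0.16 fitted a quasi-likelihood model with library as block after filterByExpr and TMM scaling. Benjamini-Hochberg adjustment was made over the kept-out genes, at an adjusted p under 0.05. Counts scaled to 1000000 (CPM) in these comparisons are TMM-scaled, while background levels and values of single clusters are not. The comparisons were suprabasal outer root sheath-like against basal cells (bulge-like included), inner root sheath-like and hair shaft-like cells against all outer root sheath cells, differentiated epidermal-like against basal cells, bulge-like against other basal cells, and melanocyte-like, immune-like and mesenchymal-like cells against all keratinocytes. The keratinocyte sums of the 10X libraries were also compared with those of the DS libraries, over all tested genes and without a block. A comparison with fewer than 3 libraries was planned as values only; its genes are counted where CPM without TMM scaling differed at least 4-fold in the same direction in each library, with at least 50 CPM on the higher side. For those with 2 libraries, an edgeR fit with 1 residual degree of freedom was added after the data were examined. A class by title group interaction was tested in the same model.

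Among 30 gene lists fixed before the data were examined (725 genes), those with at least 5 tested kept-out members were tested with camera of limma 3.58.1 (preset correlation 0.01), and beside it with an estimated correlation and with fry. Named genes followed a rule of the same date: per comparison, the 8 highest and 8 lowest called genes by fitted log2 fold change with the same direction in every library and a mean of at least 50 CPM on the higher side, plus up to 4 members of each called list with the smallest adjusted p in the direction of the list. Mitochondrially encoded, ribosomal, Y-linked, XIST, TSIX, clone-named and pseudogene symbols were left out. For 10X against DS, the rule took 6 genes each way. Values per library for genes outside this rule were chosen after they were seen. Per-library log2 ratios of CPM had a prior count of 0.5 added. A fold against sums of 0 is a lower bound with a floor of 3 counts over the group, and with 1 to 3 counts the ratio of summed counts is given with its 95% interval. Percentages of cells have exact (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only. Shares were compared between title groups by a two-sided exact permutation test over 10 splits, whose smallest p is 0.1. Its p-values are not reported, since no cell of DS 1 was named and that library entered as 0. The edgeR, DESeq2 and fry p-values measure spread between libraries, which can be less than spread between people if a donor gave more than 1 library. Camera compares the genes of a list with other genes, and the Fisher exact test of overlapping genes counts genes. A small p-value from either does not show that libraries agree. With an estimated correlation, camera uses the residual degrees of freedom of the fit, which are 1 with 2 libraries and few with 4. With 1, a list could hardly pass, and fry rests on the same degrees of freedom. A call lost in these tests is therefore not read as evidence against a list, and the camera call alone is not read as support.

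The edgeR step was tested on simulated data with 200 changed genes per comparison. It recovered 51% of 2-fold and 83% of 4-fold changes for suprabasal against basal cells, 69% and 74% for inner root sheath and shaft, and 50% and 78% for differentiated cells. With 2 libraries it recovered 2% and 20% in the bulge-like comparison, where 31.25% of calls were false, against 28% and 77% for melanocyte-like and 17% and 52% for immune-like cells. For 10X against DS these values were 1% and 47%. Clustering, naming and classes of unlike make-up between libraries were not simulated, so these values do not cover errors from those steps.

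Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, no block, leaving out each library, only DS or only 10X libraries, doublets kept, 500 genes with 10 percent mitochondrial counts, Leiden resolutions of 0.5 and 2, and clustering on all genes. A naming score of 0.25 was added after the data were examined. DS 1 gave no named cells in the reported classes. It entered a gene comparison only in 10X against DS with doublets kept and at the score of 0.25. Figures were drawn with matplotlib 3.10.9.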

Results

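Suprabasal outer root sheath-like cells differed from basal cells of the same libraries in 356 of 2305 tested genes. CASP14, a protease of cornifying keratinocytes, rose by a log2 fold change of 4.25 ± 0.32, adjusted p = 3.4e-05 (edgeR; mean ± standard error, 4 libraries), at 91.3 ± 29.1 against 8.46 ± 5.49 CPM (mean ± SD). CDKN2B, an inhibitor of the cell cycle, rose by 4.47 ± 0.35, adjusted p = 3.4e-05, and HES4, a target of Notch signalling, by 3.92 ± 0.37, adjusted p = 4.9e-05. SERPINB13, a protease inhibitor of hair follicle keratinocytes, rose by 3.34 ± 0.56, adjusted p = 0.0021, and ELOVL6, which elongates fatty acids, by 3.07 ± 0.35, adjusted p = 1.6e-04. NELL2, a secreted glycoprotein, rose by 3.94 ± 0.32, adjusted p = 3.4e-05, and TRAPPC8, of vesicle transport, by 3.38 ± 0.52, adjusted p = 0.0012. FABP5, a fatty acid carrier of differentiating keratinocytes, rose by 3.22 ± 0.59, adjusted p = 0.0036, at 11577 ± 3294 against 2260.0 ± 2487 CPM, although its change was larger in the 10X libraries. COL17A1, the hemidesmosomal collagen that also marks follicle stem cells, fell by 3.61 ± 0.34, adjusted p = 5.0e-05, at 32.5 ± 24.3 against 291 ± 170.2 CPM. DST, which ties keratin to hemidesmosomes, fell by 3.33 ± 0.31, adjusted p = 4.9e-05. CD200, a surface protein of bulge keratinocytes, fell by 4.62 ± 0.40, adjusted p = 4.1e-05, and CTNNAL1, a catenin-like protein, by 4.79 ± 0.40, adjusted p = 3.4e-05.

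Further genes were lower in suprabasal cells. The chemokine CCL2 fell by 4.49 ± 0.51, adjusted p = 1.5e-04, and the acute phase gene SAA1 by 4.39 ± 0.71, adjusted p = 0.0016. The selenoprotein gene SELENOM fell by 3.46 ± 0.32, adjusted p = 4.9e-05, and the metallothionein MT1E by 3.34 ± 0.40, adjusted p = 1.9e-04. These genes and those above kept their direction in all 4 libraries. The naming rule required this of the highest and lowest genes, so it is not read as support. Of the 356 genes, all kept out of clustering, 176 were higher and 180 lower, and before adjustment 639 of the 2305 passed nominally. DESeq2 called 256 of the 356. Without 10X 1 the number called was 30 and without 10X 2 it was 28, but only 143 and 142 of the 356 were tested there, all in the same direction. Without the replicate block, unpaired, 23 passed, and all 356 kept their direction. These refits reuse the same sums, so a kept direction is not independent support. The basal side differed between libraries, with 57 basal cells and no bulge-like cell in DS 2, 135 basal and 20 bulge-like cells in DS 3, 823 and 919 in 10X 1, and 191 bulge-like cells alone in 10X 2. The basal cluster of DS 2 scored higher for smooth muscle or pericyte markers (2.46) than for basal markers (0.85). The suprabasal side differed as well. In DS 3 it was a cluster of 105 cells led by CST6, RARRES1, SPRR1A and SPRR1B, while in the other 3 libraries KRT16 and KRT6C were among the leading genes. Clusters led by CST6 in 10X 1 (244 cells) and 10X 2 (133 cells) were left unnamed and out of the comparison.

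Junction genes rose in suprabasal cells. Of 19 tested desmosome and cell adhesion genes, 15 rose, 0 fell and 4 did not pass; adjusted over the list alone, 15 rose and 1 fell (camera adjusted p = 4.3e-08, but adjusted p = 0.44 with an estimated correlation). Among them were DSC2, a desmosomal cadherin (2.62 ± 0.26, adjusted p = 6.5e-05, 344 ± 154 against 55.4 ± 29.5 CPM), PKP1 (2.06 ± 0.27, adjusted p = 4.1e-04) and DSP, which anchors keratin at desmosomes (1.21 ± 0.19, adjusted p = 0.0012). Of 5 cornified envelope genes 3 rose, as did 3 adjusted over the list alone (camera adjusted p = 0.015, and 0.44 with an estimated correlation). IVL changed by 4.61 ± 0.71, adjusted p = 0.0012, and CSTA by 1.11 ± 0.30, adjusted p = 0.025. Of 11 proteases and inhibitors 5 rose and 0 fell; adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.0023, and 0.44 with an estimated correlation). The cathepsin CTSV changed by 2.11 ± 0.31, adjusted p = 8.2e-04, and SERPINB5 by 1.10 ± 0.23, adjusted p = 0.0067. Lipid and cholesterol synthesis rose in 8 of 17 genes, and in 10 adjusted over the list alone (camera adjusted p = 2.2e-05, and 0.44 with an estimated correlation). SQLE changed by 1.81 ± 0.34, adjusted p = 0.0044, and MSMO1 by 1.22 ± 0.27, adjusted p = 0.011. Cytokines rose in 4 of 9 genes, and in 4 adjusted over the list alone (camera adjusted p = 0.016, and 0.44 with an estimated correlation). CXCL12 changed by 2.65 ± 0.37, adjusted p = 5.6e-04, and IL18 by 1.62 ± 0.49, adjusted p = 0.042. The chemokine CCL2, which fell, is not on this list.

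Genes of attachment to the basement membrane fell in suprabasal cells: 8 of 10 tested, and 8 adjusted over the list alone (camera adjusted p = 2.2e-05, but 0.44 with an estimated correlation). LAMA3, a laminin chain, changed by -3.59 ± 0.41, adjusted p = 1.7e-04. Extracellular matrix genes fell in 6 of 7, and 6 adjusted over the list alone (camera adjusted p = 0.0002, and 0.44 with an estimated correlation). THBS1 changed by -3.15 ± 0.38, adjusted p = 1.9e-04, and POSTN by -4.22 ± 0.52, adjusted p = 2.5e-04. Of 11 bulge stem cell genes 6 fell and 1 rose, against 6 and 2 adjusted over the list alone (camera adjusted p = 0.037, and 0.46 with an estimated correlation). The Wnt inhibitor SFRP1 changed by -2.15 ± 0.37, adjusted p = 0.0023. MHC class I genes, which present peptides to T cells, fell in 5 of 11, and in 7 adjusted over the list alone (camera adjusted p = 0.00022, and 0.44 with an estimated correlation). B2M fell by 1.43 ± 0.17, adjusted p = 1.9e-04, at 947 ± 307 against 2435 ± 570.2 CPM. Immediate early genes fell in 9 of 19; adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 0.0019, and 0.44 with an estimated correlation). FOS changed by -0.58 ± 0.13, adjusted p = 0.011, and ZFP36 by -1.10 ± 0.25, adjusted p = 0.011. Of 15 heat shock genes 6 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.037, and 0.44 with an estimated correlation). HSP90AA1 changed by -0.75 ± 0.17, adjusted p = 0.011, and DNAJA1 by -0.90 ± 0.21, adjusted p = 0.012. These 11 were the lists called by camera out of 25, and none of them passed with an estimated correlation or by fry. The fry test called 2 others: oxidative stress genes, where 2 of 16 rose and 4 fell, or 2 and 5 adjusted over the list alone (fry adjusted p = 0.017), and translation factors, where 0 of 19 rose and 1 fell, the same adjusted over the list alone (fry adjusted p = 0.037). Median, mean and test differed in sign for the transcription factor, Wnt, antimicrobial and melanosome lists, none of them called.

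Inner root sheath-like and hair shaft-like cells gave 823 calls against the outer root sheath, where suprabasal and differentiated cells gave 356 and 440 against basal cells. The comparisons differ in reference cells and in recovery on simulated data, so these numbers do not rank the classes. Differentiated cells gave more calls with doublets kept (844 against 729) and at resolution 2 (764 against 699), each over 3 libraries against 4. KRTAP11-1, a keratin-associated protein of the hair cortex, rose by 7.34 ± 0.62, adjusted p = 3.2e-07 (edgeR, 4 libraries), at 2654 ± 656 against 41.8 ± 69.5 CPM. S100A3, a calcium-binding protein of the hair cuticle, rose by 6.37 ± 0.35, adjusted p = 6.7e-09, at 2465 ± 827 against 39.7 ± 40.2 CPM. CRNN, a late differentiation gene of squamous epithelium, rose by 8.26 ± 0.37, adjusted p = 1.6e-09, and the fatty acid carrier FABP4 by 6.22 ± 0.56, adjusted p = 5.7e-07. The skin DNase DNASE1L2 rose by 6.35 ± 0.44, adjusted p = 4.2e-08. The gluconeogenic enzyme FBP1 rose by 6.28 ± 0.38, adjusted p = 1.5e-08, and the ceramide enzyme DEGS2 by 5.91 ± 0.39, adjusted p = 3.3e-08. GPRC5D, a receptor known from hair keratinocytes, had 2 counts in the outer root sheath, a ratio of 576 with a 95% interval of 158 to 4776. IGFBP7, a secreted binder of growth factors, fell by 5.63 ± 0.28, adjusted p = 3.5e-09, at 12.8 ± 4.21 against 634 ± 186 CPM. MGP, an inhibitor of calcification, fell by 5.82 ± 0.31, adjusted p = 6.7e-09, and FGL2, a fibrinogen-like protein, by 6.22 ± 0.44, adjusted p = 4.5e-08. The sterol hydroxylase CYP27A1 fell by 5.60 ± 0.55, adjusted p = 1.4e-06, and the calcineurin inhibitor RCAN1 by 5.28 ± 0.53, adjusted p = 1.8e-06.

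Of 2510 kept-out genes 823 passed, 365 higher and 458 lower, with 1047 nominal, and DESeq2 called 620 of the 823. All genes named in the paragraph above kept their direction in 4 of 4 libraries, which the naming rule required of the highest and lowest genes. Leaving out 10X 1 gave 273 calls and leaving out 10X 2 gave 243, with 409 and 412 of the 823 tested, 262 and 239 of them called in the same direction. With no replicate block 166 passed. Since such refits reuse the same sums, the kept direction is not independent support.

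Transcription factors of the hair matrix and shaft rose in 7 of 10 tested genes and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.008, but adjusted p = 0.59 with an estimated correlation). DLX3 rose by 5.30 ± 0.32, adjusted p = 1.3e-08, at 118 ± 64.1 against 2.96 ± 2.0 CPM, and MSX2 by 5.06 ± 0.33, adjusted p = 3.1e-08. HOXC13, which drives hair keratin genes, rose by 2.94 ± 0.26, adjusted p = 4.0e-07, and CUX1 by 3.21 ± 0.30, adjusted p = 7.6e-07. BMP and TGF-beta genes rose in 5 of 9 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.01, and 0.59 with an estimated correlation). The ligand BMP4 changed by 4.64 ± 0.36, adjusted p = 1.4e-07, the decoy receptor BAMBI by 4.32 ± 0.29, adjusted p = 3.5e-08, and the BMP target ID3 by 2.55 ± 0.24, adjusted p = 7.6e-07. Lipid and cholesterol synthesis rose in 11 of 21 genes and fell in 2, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.008, and 0.67 with an estimated correlation). The desaturase SCD changed by 4.05 ± 0.31, adjusted p = 1.3e-07, and HMGCS1 by 1.74 ± 0.26, adjusted p = 8.0e-05.

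Stem cell and attachment genes were lower in the inner cells. Bulge stem cell genes fell in 7 of 8 and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.0017, but 0.59 with an estimated correlation). SFRP1 changed by -5.07 ± 0.33, adjusted p = 3.1e-08, SOX9, a transcription factor of the outer root sheath, by -4.11 ± 0.34, adjusted p = 2.9e-07, and NFIB by -2.66 ± 0.25, adjusted p = 8.1e-07. Hemidesmosome genes fell in 6 of 7, the same adjusted over the list alone (camera adjusted p = 0.00073, and 0.59 with an estimated correlation). COL17A1 changed by -3.07 ± 0.42, adjusted p = 4.2e-05, and the integrin ITGB1 by -1.58 ± 0.22, adjusted p = 5.1e-05. Contractile and cytoskeletal genes fell in 11 of 13, the same adjusted over the list alone (camera adjusted p = 8.9e-08, or 1.1e-07 without DS 2, whose outer root sheath included a cluster with smooth muscle markers, and 0.59 with an estimated correlation). CAV1 of caveolae changed by -4.29 ± 0.26, adjusted p = 1.3e-08, and VIM, a filament protein found also in mesenchymal cells, melanocytes and leukocytes, by -4.13 ± 0.30, adjusted p = 6.9e-08. Matrix genes fell in 4 of 5 and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.036, and 0.59 with an estimated correlation). TIMP3 changed by -3.83 ± 0.32, adjusted p = 2.5e-07.

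MHC class I genes fell in the inner cells in 8 of 11, the same adjusted over the list alone (camera adjusted p = 0.0034, but 0.6 with an estimated correlation). B2M changed by -2.11 ± 0.24, adjusted p = 6.8e-06 (419 ± 96.0 against 1808 ± 624 CPM), HLA-B by -2.66 ± 0.37, adjusted p = 5.2e-05, and the immunoproteasome subunit PSMB8 by -2.07 ± 0.28, adjusted p = 4.0e-05. Low MHC class I in the growing hair bulb is part of its known immune privilege, yet privilege factors also fell, in 4 of 7 genes, the same adjusted over the list alone (camera adjusted p = 0.0497, and 0.59 with an estimated correlation). CD59, a complement inhibitor, changed by -2.15 ± 0.28, adjusted p = 2.1e-05. Cytokines fell in 6 of 7 genes, the same adjusted over the list alone (camera adjusted p = 0.00036, and 0.59 with an estimated correlation). TNFSF10 changed by -3.87 ± 0.31, adjusted p = 2.0e-07, and CXCL12 by -5.13 ± 0.43, adjusted p = 2.9e-07. Antimicrobial genes fell in 5 of 7 and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.036, and 0.59 with an estimated correlation). CHI3L1 changed by -2.62 ± 0.27, adjusted p = 2.7e-06, and the defensin DEFB1 by -3.12 ± 0.46, adjusted p = 8.0e-05. Immediate early genes fell in 14 of 20; adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 0.00074, and 0.75 with an estimated correlation). DUSP1 changed by -2.52 ± 0.27, adjusted p = 3.5e-06, and MYC by -2.72 ± 0.34, adjusted p = 1.6e-05. Of 25 lists 12 were called, and 0 with an estimated correlation or by fry. The hormone and oxidative phosphorylation lists, not called, had medians of -0.01 and 0.07 but means of 0.11 and -0.05.

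Differentiated epidermal-like cells differed from basal cells in 440 of 2229 tested genes. SERPINB3, an inhibitor of cysteine proteases in squamous epithelium, rose by 8.03 ± 0.48, adjusted p = 9.4e-09 (edgeR, 4 libraries), at 181 ± 86.3 against 0.230 ± 0.460 CPM, and SERPINB4 rose by 5.90 ± 0.52, adjusted p = 4.8e-07. DEGS2, which makes phytoceramides, rose by 6.78 ± 0.48, adjusted p = 4.8e-08, and the neuropeptide gene NMU by 5.90 ± 0.44, adjusted p = 1.0e-07. The calcium-binding CHP2 rose by 6.09 ± 0.47, adjusted p = 1.6e-07, and the esterase-like AADACL2 by 6.26 ± 0.61, adjusted p = 1.4e-06. The trypsin gene PRSS3 rose by 5.70 ± 0.57, adjusted p = 1.8e-06, and TMEM40 by 5.50 ± 0.45, adjusted p = 3.0e-07. CYP1B1, an enzyme of steroid and retinoid metabolism, fell by 6.72 ± 0.39, adjusted p = 9.4e-09. IGFBP7 fell by 5.78 ± 0.40, adjusted p = 3.9e-08, at 23.1 ± 14.1 against 927 ± 592 CPM. SFRP1 fell by 6.08 ± 0.40, adjusted p = 2.6e-08, and CCL2 by 6.32 ± 0.42, adjusted p = 3.2e-08. COL17A1 fell by 5.68 ± 0.49, adjusted p = 3.7e-07, THBS1 by 5.85 ± 0.55, adjusted p = 9.2e-07, and CTNNAL1 by 5.91 ± 0.50, adjusted p = 3.1e-07. BASP1, a membrane protein, had 1 count in differentiated cells and was higher in basal cells by a ratio of 194, with a 95% interval of 34.7 to 7662.

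Of the 440 genes that differed between differentiated and basal cells, all kept out of clustering, 213 were higher and 227 lower, and DESeq2 called 351 of them; 709 of the 2229 passed nominally. The genes named above kept their direction in 4 of 4 libraries, but as highest and lowest genes they had been chosen for this. Without 10X 1 the count was 59 and without 10X 2 it was 66, where 152 of the 440 were tested each time, all in the same direction. With no replicate block 70 passed. Here too the refits reuse the same sums, so the kept direction is not independent support. The basal side was the same mix as for suprabasal cells, from no bulge-like cell in DS 2 to bulge-like cells alone in 10X 2. The differentiated side differed too. In 10X 1 it was 126 cells with a median of 26914 UMIs, while 369 cells led by KRT10 and KRT1 were left unnamed, and in 10X 2 it held 109 cells with a median of 1367 UMIs among its 197.

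Lists of barrier genes rose in the differentiated cells. Cornified envelope genes rose in 4 of 5, and in 5 adjusted over the list alone (camera adjusted p = 0.00017, but adjusted p = 0.38 with an estimated correlation). IVL rose by 6.0 ± 0.78, adjusted p = 3.2e-05, CSTA by 3.44 ± 0.41, adjusted p = 1.1e-05 and SPRR1A by 3.80 ± 0.62, adjusted p = 2.8e-04. SPRR1B rose by 3.75 ± 0.67, adjusted p = 6.4e-04, although in the inner cells its change differed between DS and 10X. Proteases and inhibitors rose in 9 of 14; adjusted over the list alone 10 rose and 1 fell (camera adjusted p = 6.5e-07, and 0.38 with an estimated correlation). SPINK5, whose loss causes Netherton syndrome, changed by 3.60 ± 0.61, adjusted p = 3.9e-04, and SLPI by 2.98 ± 0.38, adjusted p = 2.7e-05. Desmosome genes rose in 9 of 19 and fell in 3, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.018, and 0.54 with an estimated correlation). DSG1 changed by 3.06 ± 0.49, adjusted p = 2.4e-04 (264 ± 59.1 against 61.1 ± 57.8 CPM) and DSC1 by 1.75 ± 0.36, adjusted p = 0.002. Lipid synthesis rose in 9 of 17, or 12 adjusted over the list alone (camera adjusted p = 0.00017, and 0.54 with an estimated correlation). CERS3 and ELOVL4, of barrier ceramides, changed by 3.0 ± 0.45, adjusted p = 1.2e-04, and 2.35 ± 0.52, adjusted p = 0.0032. In the list of hair matrix transcription factors 1 of 6 rose, or 5 adjusted over the list alone; it was GRHL1, a regulator of epidermal desmosomal cadherins and not a hair-specific factor, at 2.13 ± 0.36, adjusted p = 3.5e-04 (camera adjusted p = 0.0033, and 0.38 with an estimated correlation).

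MHC class I went the other way from the suprabasal and inner cells: 4 of 13 genes rose, or 5 adjusted over the list alone (camera adjusted p = 0.03, but 0.54 with an estimated correlation). B2M changed by 1.45 ± 0.29, adjusted p = 0.0015 (7227 ± 2886 against 2368 ± 530.4 CPM) and HLA-B by 1.32 ± 0.29, adjusted p = 0.0035. The rise was not even over libraries. Summed over the 4 called genes, it was small in 10X 1, at 5479 against 4008 CPM, and larger in 10X 2, at 6856 against 3108 CPM. Antimicrobial and alarmin genes rose in 5 of 7 and 1 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.018, and 0.54 with an estimated correlation). Without 10X 2 the direction of this list reversed and the call was lost (adjusted p = 0.99). S100A7 changed by 4.07 ± 0.59, adjusted p = 8.7e-05 (6013 ± 5631 against 398 ± 428 CPM) and S100A8 by 4.11 ± 0.68, adjusted p = 3.1e-04. Glycolysis rose in 3 of 13 genes and fell in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.035, and 0.54 with an estimated correlation). The glucose transporter SLC2A1 changed by 1.72 ± 0.29, adjusted p = 3.8e-04. Oxidative phosphorylation rose in 2 of 32, ATP5F1B at 0.89 ± 0.24, adjusted p = 0.014 and COX5B at 0.76 ± 0.25, adjusted p = 0.037, and in 0 adjusted over the list alone (camera adjusted p = 0.01, and 0.65 with an estimated correlation).

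Stem cell, attachment, matrix and contractile lists fell in differentiated cells. Bulge stem cell genes fell in 5 of 7, or 6 adjusted over the list alone (camera adjusted p = 0.00013, but 0.38 with an estimated correlation). NFIB changed by -3.89 ± 0.34, adjusted p = 4.6e-07. Hemidesmosome genes fell in 6 of 7, the same adjusted over the list alone (camera adjusted p = 3.8e-06, and 0.38 with an estimated correlation). ITGB1 changed by -3.37 ± 0.30, adjusted p = 5.9e-07, and DST by -5.10 ± 0.55, adjusted p = 4.1e-06. All 5 matrix genes fell, also adjusted over the list alone (camera adjusted p = 3.8e-06, and 0.38 with an estimated correlation). SPARC changed by -4.35 ± 0.49, adjusted p = 6.9e-06. Contractile genes fell in 9 of 12, the same adjusted over the list alone (camera adjusted p = 6.5e-07, and 0.38 with an estimated correlation). MYL9 changed by -4.31 ± 0.40, adjusted p = 7.6e-07, and TPM2, both also strong in smooth muscle, by -3.83 ± 0.45, adjusted p = 9.7e-06. The basal cluster of DS 2 carried smooth muscle markers, and at resolution 2 a DS 2 cluster of 8 cells led by ACTG2, ACTA2 and TAGLN was split off. Without DS 2 the contractile list was still called (camera adjusted p = 2.6e-07). Of 23 lists 13 were called by camera, and none of these passed with an estimated correlation or by fry. The fry test called 1 other, melanosome genes, where 1 of 8 rose and 2 fell, or 1 and 3 adjusted over the list alone (fry adjusted p = 0.0012). Immediate early genes and translation factors had medians of -0.11 and -0.01 while the test pointed upward, without a call.

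**Figure D1:**
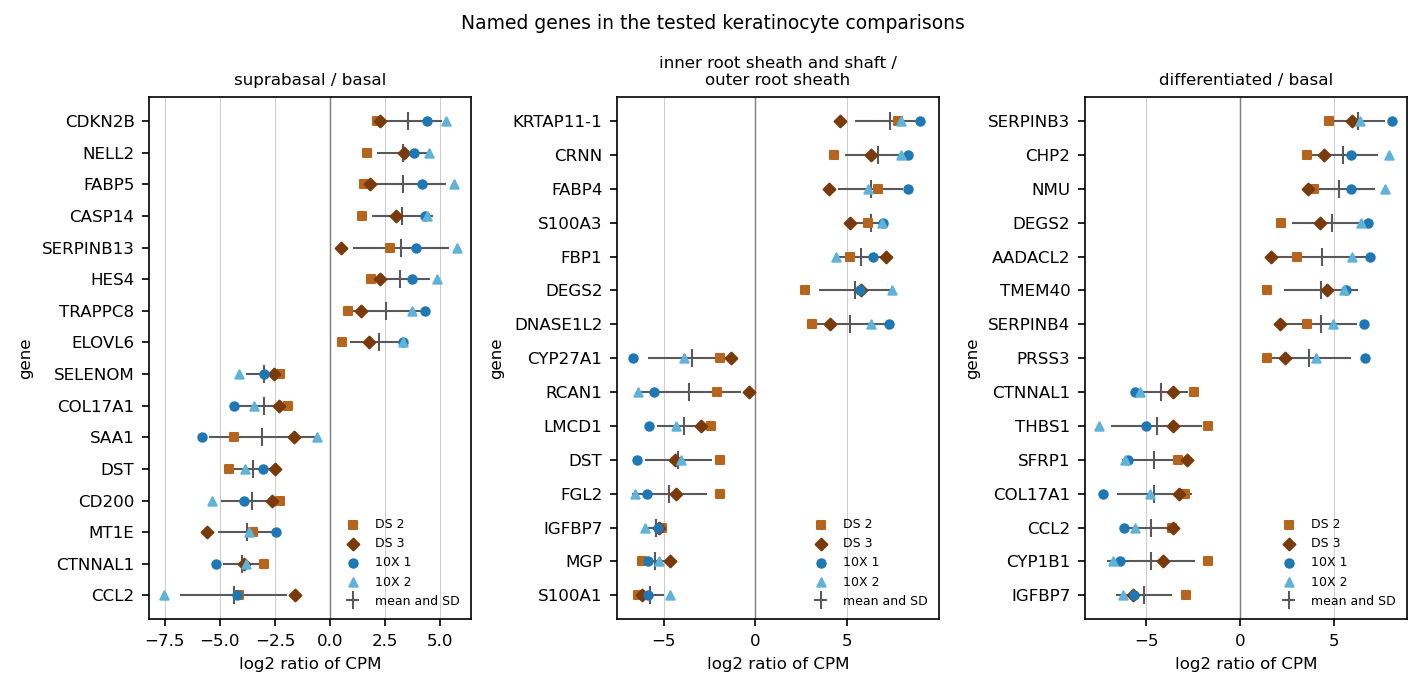
Log2 ratio of CPM of named genes in the keratinocyte comparisons, as points of single libraries with mean and SD over 4 libraries. A prior count of 0.5 was added, and genes with 3 or fewer counts on a side were left out.

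Bulge-like cells could be compared with other basal cells in DS 3 (20 against 135 cells) and 10X 1 (919 against 823 cells). The class did not hold the same cells in both. In DS 3 it was 1 cluster led by ANGPTL7, COMP and TIMP3, as was a cluster of 190 cells in 10X 1. A DS 3 cluster of 45 cells led by DIO2 and KRT15, nearer to the main bulge-like cluster of 729 cells in 10X 1 by its leading genes, was named basal and counted on the other side. At resolution 2 a DS 3 cluster of 21 cells led by DIO2 and KRT15 was named bulge-like.

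MGP was at 1172 against 85.0 CPM in DS 3 and 638 against 6.24 CPM in 10X 1. Within the bulge-like cells of 10X 1, MGP and TIMP3 were much higher in the smaller cluster than in the larger one, as given under Other observations. IGFBP7 was at 2979 against 614 CPM in DS 3 and 1258 against 21.3 CPM in 10X 1, and THBS1, a matrix protein that activates TGF-beta, at 146 against 18.9 CPM in DS 3 and 191 against 12.6 CPM in 10X 1. LHX2, a transcription factor that maintains follicle stem cells, had a log2 ratio of 3.82 in 10X 1, and TBX1, linked to stem cell self-renewal, of 3.21. The matrix protein FBLN2 reached 4.20 in 10X 1, and TGFB2, a signal in stem cell activation, 4.01. In DS 3 each of these 4 genes had at most 2 counts on a side, which gives no direction. Alarmins were lower: S100A8 was at 122 against 3884 CPM in DS 3 and 175 against 2929.7 CPM in 10X 1. S100A9 was at 0 against 983 CPM in DS 3 and 128 against 4533 CPM in 10X 1, and S100A7 at 24.4 against 728 CPM in DS 3 and 83.7 against 1903 CPM in 10X 1. EHF, an epithelial transcription factor, was at 0 against 293 CPM in DS 3 and 2.78 against 167 CPM in 10X 1. The chemokine CCL20 was at 0 against 198 CPM in DS 3 and 3.38 against 76.6 CPM in 10X 1. The bulge-like side of DS 3 held only 27716 UMIs. Its values for THBS1, S100A8, S100A9, S100A7, EHF and CCL20 therefore rest on a few counts or none. KRT19, often used as a bulge marker, was at 165 against 3.04 CPM in 10X 1, with 1 count in DS 3.

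Of 1637 genes considered, 47 differed at least 4-fold in both libraries, 36 higher and 11 lower in bulge-like cells. With 27716 UMIs on the bulge-like side of DS 3, a few counts decide whether a gene enters this number. LYPD6, of the Ly6 family, was higher by a ratio of 70.5 (95% interval 12.1 to 2838), IGFBP3 lower by 157 (53.5 to 764), and SAA2 at least 19.9-fold lower. By the edgeR fit added over 2 libraries, with 31.25% false calls in simulated data, matrix genes were higher in 5 of 16 and bulge stem cell genes in 4 of 23, or 7 and 5 adjusted over the list alone, with TIMP3 at log2 ratios of 3.55 in DS 3 and 2.04 in 10X 1 (camera adjusted p = 8.9e-11 and 1.3e-05, but 0.70 each with an estimated correlation). Antimicrobial genes were lower in 6 of 9 and proteases in 6 of 15, or 7 and 10 adjusted over the list alone (camera adjusted p = 1.5e-10 and 4.7e-05, and 0.70 with an estimated correlation). MHC class I had 0 of 17 members called, and 3 lower adjusted over the list alone, at a median log2 change of -1.18 (camera adjusted p = 7.3e-06, and 0.70 with an estimated correlation). Among the remaining 6 called lists, hemidesmosome genes were higher at a median of 0.52, and oxidative phosphorylation (-0.78), glycolysis (-0.75), matrix transcription factors (-0.72), translation factors (-0.59) and heat shock genes (-0.56) were lower. In these 6 lists at most 1 member was called, and adjusted over the list alone also at most 1, and the only heat shock member called was higher. Their camera adjusted p ran from 3.6e-07 to 0.03, and was 0.70 with an estimated correlation. The desmosome, BMP, privilege factor and contractile lists, none of them called, had medians and means of different sign.

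Melanocyte-like cells were compared with keratinocytes in 10X 1 (295 against 2386 cells) and 10X 2 (67 against 584 cells). TRPM1, a melanocyte ion channel, was at 269.8 against 0.270 CPM in 10X 1 and 304 against 0.522 CPM in 10X 2. PMEL, a melanosome marker, was still at 7.51 CPM in keratinocytes of 10X 1 and 4.88 CPM in those of 10X 2, and background RNA lowers such ratios. EDNRB, the endothelin receptor that guides melanoblasts, was at 390.2 against 0.854 CPM in 10X 1 and 440.2 against 0.261 CPM in 10X 2, and CAPN3, a calpain expressed in melanocytes, at 1401 against 3.46 CPM in 10X 1 and 1290.0 against 3.65 CPM in 10X 2. PAX3, a transcription factor of the melanocyte lineage, was at least 1007-fold higher, and SLC24A5, a pigmentation exchanger, had a ratio of 5953 (95% interval 1061 to 235838). The interferon-induced IFITM2 was at 234 against 11.2 CPM in 10X 1 and 201 against 12.3 CPM in 10X 2 and IFI6 at 117 against 6.25 CPM in 10X 1 and 157 against 3.91 CPM in 10X 2. CD44, a hyaluronan receptor, was at 776 against 225 CPM in 10X 1 and 747 against 231 CPM in 10X 2. Junction genes were lower, with PERP at 299.9 against 3714 CPM in 10X 1 and 225 against 4282 CPM in 10X 2. DSP was at 32.5 against 748 CPM in 10X 1 and 6.83 against 917 CPM in 10X 2, and GJB2 at 8.43 against 367 CPM in 10X 1 and 3.41 against 586 CPM in 10X 2. TPT1, a growth-linked gene, had log2 ratios of -1.24 in 10X 1 and -1.47 in 10X 2, and EEF1A1 of -0.82 in 10X 1 and -0.98 in 10X 2.

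Of 1573 genes considered, 270 differed at least 4-fold in both libraries, 153 higher and 117 lower in melanocyte-like cells. By the edgeR fit added over 2 libraries, melanosome genes were higher in 23 of 26 with 1 lower, interferon response in 13 of 22 with 2 lower, and MHC class I in 8 of 18 with 0 lower. Adjusted over the list alone these were 23 and 1, 15 and 2, and 8 and 1 (camera adjusted p = 1.2e-17, 2.6e-06 and 0.039, but 0.66 each with an estimated correlation). Immune surface genes were higher in 6 of 9 with 1 lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.017, and 0.66 with an estimated correlation). The other 15 of 19 called lists were lower, among 29 tested. Desmosome genes were lower in 17 of 21 with 2 higher, or 18 and 2 adjusted over the list alone (camera adjusted p = 2.5e-10, and 0.66 with an estimated correlation). Cornified envelope genes were lower in 10 of 11, bulge stem cell genes in 19 of 23 with 1 higher, and proteases in 14 of 17 with 2 higher. Lower too were antimicrobial genes in 8 of 9 and Wnt genes in 8 of 18, all 5 with the same counts adjusted over the list alone (camera adjusted p = 5.4e-06, 9.6e-07, 4e-05, 1.6e-06 and 0.049, and 0.66 with an estimated correlation). Hedgehog genes were lower in 4 of 7, hormone genes in 11 of 18 with 2 higher, and growth factor genes in 13 of 22 with 3 higher. Lower as well were cytokines in 10 of 16 with 3 higher, contractile genes in 9 of 15 with 3 higher, and translation factors in 11 of 20. Oxidative phosphorylation was lower in 7 of 32 with 1 higher, hemidesmosome genes in 11 of 21 with 5 higher and matrix transcription factors in 11 of 19 with 2 higher. Adjusted over the list alone, growth factor genes were lower in 14, translation factors in 12, hemidesmosome genes in 12 with 6 higher, and matrix transcription factors in 11 with 3 higher, with the rest the same (camera adjusted p from 0.0011 to 0.042, and 0.66 to 0.70 with an estimated correlation).

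Immune-like cells, T cell-like with Langerhans-like or macrophage-like cells, were compared with keratinocytes in 10X 1 (144 against 2386 cells) and 10X 2 (54 against 584 cells). In 10X 1 they were 92 T cell-like and 52 Langerhans-like cells, with CD74, on the MHC class II list, at 1068 and 26200 CPM. In 10X 2 they were 40 T cell-like and 14 macrophage-like cells, with CD74 at 545 and 25794 CPM. The sums therefore do not describe T cells alone. SRGN, the proteoglycan of leukocyte granules, was at 2356 against 1.94 CPM in 10X 1 and 1402 against 0.230 CPM in 10X 2, and LAPTM5, a lysosomal protein of blood cells, at 881 against 1.07 CPM in 10X 1 and 936 against 1.15 CPM in 10X 2. HLA-DQB1, of MHC class II, was at 3468 against 1.51 CPM in 10X 1 and 2033 against 6.45 CPM in 10X 2, and the inflammatory cytokine IL1B at 1149 against 1.11 CPM in 10X 1 and 475 against 0.230 CPM in 10X 2. CXCL8, which attracts neutrophils, was at 3383 against 38.7 CPM in 10X 1 and 1482 against 6.91 CPM in 10X 2, and KLRB1, a receptor of innate-like T cells, at 292 against 0.436 CPM in 10X 1 and 433 against 0.230 CPM in 10X 2. NR4A2 and KLF6, genes induced by stimulation, had log2 ratios of 4.46 in 10X 1 and 4.87 in 10X 2, and of 2.66 in 10X 1 and 2.61 in 10X 2. HLA-B was at 3676 against 627 CPM in 10X 1 and 2155 against 411 CPM in 10X 2. CD86, a costimulator of T cells, was at least 866-fold higher and the lipid-presenting CD1B at least 828-fold higher. S100A1 was at least 17.4-fold lower, GAS1 17.6-fold and ID4 10.9-fold. The gap junction gene GJB6 was at 10.2 against 332 CPM in 10X 1 and 18.8 against 640.4 CPM in 10X 2. The immune sums shifted the median log2 change to -0.15, and the values are not corrected for this shift.

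Of 1452 genes considered, 346 differed at least 4-fold in both libraries, 208 higher and 138 lower in immune-like cells. By the edgeR fit added over 2 libraries, immune surface genes were higher in 28 of 29, MHC class II in 17 of 17 and MHC class I in 15 of 19. Adjusted over the list alone these were 28, 17 and 16 (camera adjusted p = 1.7e-40, 9.1e-30 and 8.1e-10, but 0.60 each with an estimated correlation). Interferon response was higher in 11 of 19 with 2 lower, cytokines in 13 of 20 with 6 lower, privilege factors in 8 of 13 with 2 lower and immediate early genes in 12 of 25 with 1 lower. Adjusted over the list alone these were 11 and 3, 13 and 6, 8 and 2, and 13 and 1 (camera adjusted p = 0.00032, 0.0002, 0.0037 and 0.0071, and 0.60 with an estimated correlation). LGALS9, a privilege factor also made by antigen-presenting cells, was at 84.7 against 0.516 CPM in 10X 1 and 75.3 against 0.922 CPM in 10X 2. The other 11 of 18 called lists were lower, among 28 tested. Desmosome genes were lower in 18 of 21, antimicrobial genes in 7 of 8, oxidative phosphorylation in 7 of 32, and bulge stem cell genes in 15 of 22 with 2 higher. Also lower were proteases in 12 of 17 with 1 higher, contractile genes in 10 of 15 with 2 higher and growth factor genes in 14 of 23 with 3 higher, with the same lower counts adjusted over the list alone. Hemidesmosome genes were lower in 12 of 19, cornified envelope genes in 7 of 11, Wnt genes in 7 of 17 and matrix genes in 11 of 20 with 2 higher. These were 13, 9, 8 and 13 adjusted over the list alone (camera adjusted p from 2.5e-12 to 0.017 over these 11, and 0.60 to 0.69 with an estimated correlation). BMP genes, not called, had a median of -1.23 while the test pointed upward.

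Mesenchymal-like cells reached 20 cells only in 10X 1 (78 against 2386 keratinocytes), so their comparison rests on 1 library. Their cluster was named fibroblast-like at a score of 4.97, but scored 3.1 for smooth muscle or pericyte markers. At resolution 2 there were 38 fibroblast-like and 74 smooth muscle-like cells instead. PRRX1, a transcription factor of dermal fibroblasts, was at least 2351-fold higher, the Wnt amplifier RSPO3 at least 1158-fold, the Wnt inhibitor DKK2 at least 948-fold and the dermal TBX15 at least 702-fold. PTGDS, which makes prostaglandin D2, was also higher, at a log2 ratio of 12.97 in 10X 1. Of 1655 genes considered 220 were at least 4-fold higher. KRT14 in these cells was at 31.1% of its keratinocyte level, so their levels of keratinocyte genes are not read here.

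**Figure D2:**
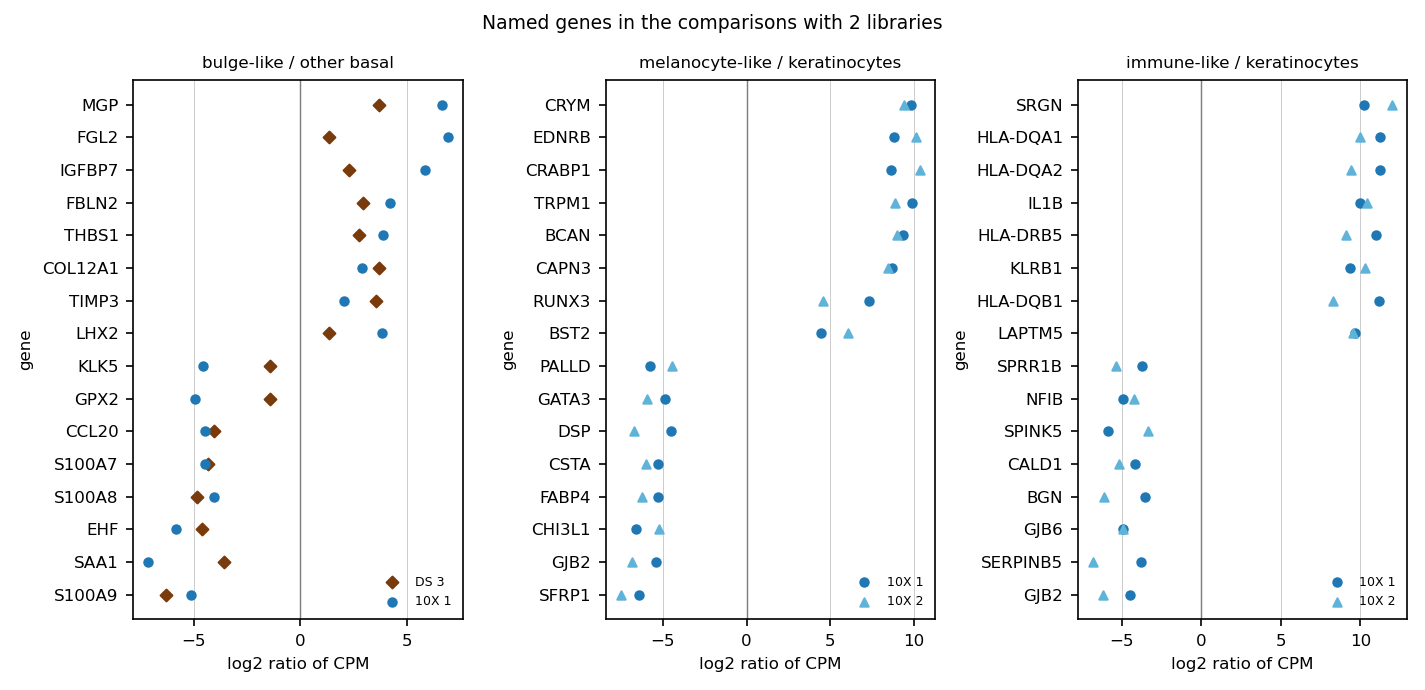
Log2 ratio of CPM of named genes with the same direction in both libraries, in comparisons with 2 libraries, shown as points of single libraries with no mean. A prior count of 0.5 was added, and genes with 3 or fewer counts on a side over both libraries were left out; the DS 3 points of FBLN2, COL12A1, LHX2, KLK5 and GPX2 rest on 3 or fewer counts.

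Shares of cell classes describe suspensions sorted by FACS for live cells, not tissue. Basal-like cells were 22.8% of cells used in DS 2 (exact 95% interval 17.7 to 28.5), 27.9% in DS 3 (23.9 to 32.1), and 20.7% in 10X 1 (19.4 to 22.0). In 10X 2 no cluster was named basal, but a cluster of 170 cells left unnamed was named basal at a score of 0.25. Bulge-like cells were 23.1% in 10X 1 (21.8 to 24.4), 17.7% in 10X 2 (15.4 to 20.1) and 4.13% in DS 3 (2.54 to 6.31), and none were named in DS 2. At resolution 2 an unnamed DS 2 cluster of 17 cells scored best as bulge-like. The low DS 3 value depends on the 45 cells led by DIO2 and KRT15 being named basal. Melanocyte-like cells were 7.41% (6.62 to 8.27) in 10X 1, 6.2% (4.84 to 7.80) in 10X 2, 2% in DS 2 and 1.86% in DS 3. T cell-like cells were 2.31% (1.87 to 2.83) in 10X 1 and 3.70% (2.66 to 5.00) in 10X 2, and none were named in DS. Endothelial-like and mesenchymal-like cells, 1.96% each (1.55 to 2.44), were named only in 10X 1.

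Keratinocyte classes past the basal layer were named in 4 libraries. Suprabasal cells were 18.8% in DS 2, 21.7% in DS 3, 6.96% in 10X 1 and 11.6% in 10X 2, but these are not the same cells throughout, since cells led by CST6 bore this name in DS 3 and none in the 10X libraries. Differentiated cells were 22.0%, 19.4%, 3.17% and 18.2%, where the low value of 10X 1 depends on 369 cells led by KRT10 and KRT1 being left unnamed. Inner root sheath-like cells were 4.80%, 5.17%, 1.36% and 1.94% in the same order, and hair shaft-like cells 10.4%, 8.06%, 4.70% and 4.63%. Cycling-like cells made up 6.40%, 6.40%, 4.37% and 5.74%, and sweat gland-like cells 12.8%, 5.37%, 0.452% and 1.02%. Unnamed cells were 100% (91.2 to 100) of DS 1, 0 in DS 2 and DS 3, 20.3% (19.1 to 21.6) of 10X 1 and 28.0% (25.4 to 30.8) of 10X 2. A basal cluster of DS 2 and a differentiated cluster of 10X 2 had low UMI counts, with medians of 567 and 1367 against library medians of 984.5 and 6292. Background RNA was present, since KRT14 in T cell-like cells reached 3.21% of its keratinocyte level in 10X 1 and 3.29% in 10X 2.

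**Figure D3:**
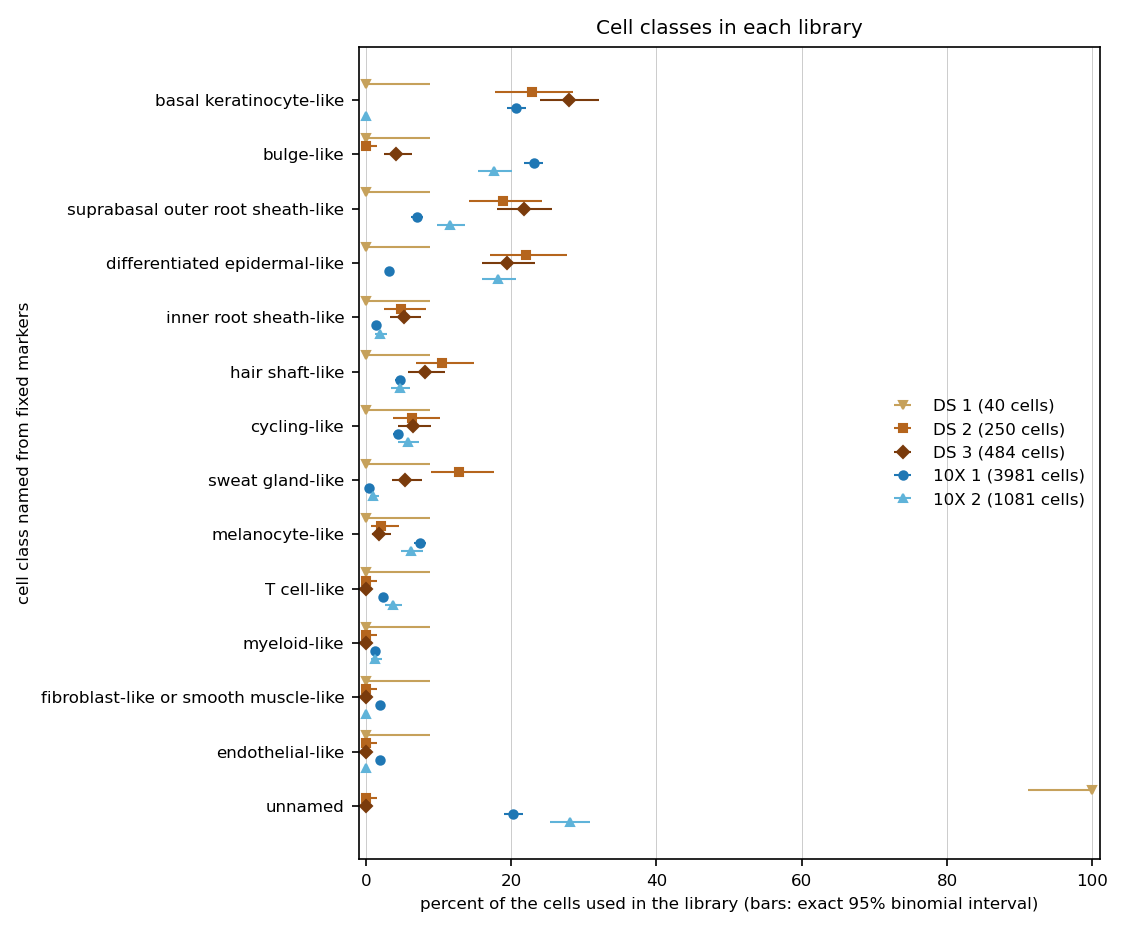
Percentage of cells used in each class, per library, with exact 95% binomial intervals. Cells had been sorted by FACS for live cells before the libraries were made.

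Keratinocytes of the 10X and DS libraries differed in 2261 of 9885 tested genes, 1380 higher and 881 lower in 10X (edgeR, 2 against 2 libraries, 3940 nominal), a difference that cannot be separated from donor, preparation, the counting of reads or the different classes within the sums. UQCR11, of respiratory complex III, had 727 ± 44.3 CPM in DS and 0 in 10X, at least 6982-fold lower, and SEM1, a proteasome subunit, was at least 6432-fold lower. NDUFB8, of complex I, was at least 4414-fold lower, TMBIM4 1871-fold and IER3IP1 1125-fold. UQCR11, NDUFB8, TMBIM4 and IER3IP1 overlap another gene on the same strand in the GENCODE annotation, so their counts of 0 are not read as low expression. PSMA2, another proteasome subunit, had 1 count in 10X and 275 CPM in DS. ITGB4, the hemidesmosomal integrin, had 50.7 ± 8.98 CPM in 10X and 0 in DS, at least 11.6-fold higher, the polymerase subunit POLR2F was at least 28.7-fold higher, MTRNR2L10 84.0-fold and STMN3 18.1-fold. The helicase EIF4A1 had 879 ± 147 CPM in 10X and 1 count in DS. At its DS level SEM1 would have had 19295 counts in 10X. Whether counts of SEM1, PSMA2, ITGB4, POLR2F, MTRNR2L10, STMN3 and EIF4A1 lie under other names was not checked. Their folds are therefore not read as differences in expression either. Leaving out 1 library gave 1144 calls without DS 2, 792 without DS 3, 1545 without 10X 1 and 1341 without 10X 2, and the median log2 change was 0.24.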

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

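The DESeq2 counts of the interaction and the split counts below were made after the data were examined, and these tests were not in the first plan. The rule for too distant samples could not be applied, since the title groups hold 3 and 2 libraries. No treatment or donor is stated, so no biological explanation was tested for any pattern here.

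Class changes were compared between 10X and DS over 2 against 2 libraries, a test whose power was not measured, so a low number of calls does not show that the platforms agree. The edgeR interaction called 1 gene for suprabasal against basal, 2 for inner root sheath and shaft and 1 for differentiated cells, against 117, 221 and 192 nominal calls and 11, 6 and 15 calls by DESeq2. FABP5 differed by a log2 of 3.24 in suprabasal cells (adjusted p = 0.046), with log2 ratios of 1.53 in DS 2, 1.82 in DS 3, 4.16 in 10X 1 and 5.62 in 10X 2. In differentiated cells FABP5 differed by 4.75 (adjusted p = 0.00026), at -0.74 and -0.36 in DS 2 and DS 3 but 4.43 and 4.01 in 10X 1 and 10X 2. In inner root sheath and shaft cells CST6 differed by 4.61 (adjusted p = 0.010) and SPRR1B by 4.14 (adjusted p = 0.029). CST6 in the outer root sheath was at 8918 CPM in DS 2 and 15698 in DS 3, against 378 in 10X 1 and 1417 in 10X 2. The clusters of the 10X libraries with the most CST6 carried no class name and were outside the comparison.

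Cells without a class name were left out of the gene comparisons: 40 in DS 1, 808 in 10X 1 and 303 in 10X 2. The 40 cells of DS 1 still held UMIs of keratinocyte markers, 206 of basal, 47 of suprabasal, 1540 of differentiated, 63 of inner root sheath and 24 of hair shaft markers. A naming score of 0.25 named 17.5% of DS 1, 89.0% of 10X 1 and 87.7% of 10X 2.

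The number of calls was compared with splits of the same 8 sums into other groups of 4. In each comparison 32 of 35 splits could be fitted, and 1 of 32 had as many calls as the real split, which was the real split itself. The next highest counts were 229 for suprabasal, 223 for inner root sheath and shaft and 293 for differentiated cells. The classes were made by clustering on expression, which favours the real split from the start, so these counts are not read as support for the calls.

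MHC class I genes fell in suprabasal cells (5 of 11) and inner cells (8 of 11) and rose in differentiated cells (4 of 13). All 3 lists were called by camera but lost the call with an estimated correlation (adjusted p = 0.44, 0.60 and 0.54). With the other most abundant genes left out (199, 199 and 197 genes), the called members still had median log2 changes of -1.64, -1.81 and 1.25. Both fits were TMM-scaled, so this refit alone decides little. The share of counts outside the 200 most abundant genes differed between sides by log2 -0.163 to 0.00765, -0.0119 to 0.172 and -0.293 to -0.0739. These shifts are smaller than the changes, so a few genes taking most of the counts cannot account for them. The leukocyte genes SRGN, LAPTM5, ITGB2 and CORO1A showed at most 1.36, 0.806 and 0.143 percent of the immune RNA needed in the 10X libraries, so free RNA or doublets from immune cells are excluded there. The DS libraries had no named immune cells and were not tested, and at resolution 2 a DS 3 cluster of 23 cells was led by CCL3, HLA-DRB1 and CD74. No biological explanation was tested.

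Genes at 0 in the keratinocytes of one title group had at least 50 CPM in the other: 8 at 0 in 10X and 4 at 0 in DS. Of these 12, 50% overlap another gene on the same strand, against 15.8% of 9868 other tested genes, a ratio of 3.16 (Fisher exact p = 0.0061), which fits reads of overlapping genes being counted differently for these genes. Overlaps were taken from the GENCODE annotation, which is not known to be the one used for counting. All 6 overlapping genes are among the 8 at 0 in 10X, and the explanation covers none of the 4 at 0 in DS (ITGB4, MTRNR2L10, POLR2F and STMN3) and not the other 2 at 0 in 10X, SEM1 and a clone-named gene. Depth is excluded, since the lowest expected count was 34.9. No biological explanation was tested.

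Of 20 immediate early genes 14 fell in inner root sheath and shaft cells, a list called by camera (adjusted p = 0.00074) but not with an estimated correlation (adjusted p = 0.75) or by fry (adjusted p = 0.17). If stress of dissociation was weaker in these cells, heat shock genes should have been lower as well, and their median log2 change was -0.31. With 6 of 15 lower and 1 higher, and no call for the list, the test cannot tell. In suprabasal cells camera called both the immediate early and the heat shock list lower, at medians of -0.71 and -0.37. Whether weaker stress of dissociation lay behind this was not tested. No biological explanation was tested.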

How the results depend on the processing

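The naming score of 0.25, the DESeq2 counts of the interaction and the edgeR fits over 2 libraries (bulge, melanocyte, immune) were chosen after the data were examined. The other alternatives were fixed before. Of 4336 values of named genes under alternatives 4034 stayed the same, 302 were weaker and 0 reversed. These genes were chosen as called in the same libraries, so the lack of reversals is not read as support. A gene not tested under an alternative gave no value there. For gene lists 151 of 361 were the same, 209 weaker and 1 reversed, and for summary values 138 of 225 were the same, 61 moved, 12 weaker and 14 reversed. Where no reason is given, the cause was not tested.

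Suprabasal against basal had 356 calls. It had 797 without the low-count filter, 646 with only 10X, 1418 with 500 genes and 10 percent mitochondrial counts, 734 at resolution 0.5, 682 with clustering on all genes and 591 at the score of 0.25. With only DS, where fewer genes and libraries are tested, 0 passed by edgeR (76 nominal). Without the replicate block, unpaired, 23 passed. Leaving out 1 library gave 28 to 514 calls, the lowest without 10X 2.

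Inner root sheath and shaft against outer root sheath had 823 calls. It had 1748 without the low-count filter, 1838 with only 10X, 191 with only DS, 2512 with 500 genes and 10 percent, and 1346 with clustering on all genes. Without the replicate block, unpaired, 166 passed. Leaving out 1 library gave 243 to 1356 calls.

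Differentiated against basal had 440 calls. It had 1138 without the low-count filter, 1192 with only 10X, 844 with doublets kept, 1155 with 500 genes and 10 percent, 714 at resolution 0.5, 764 at resolution 2 and 796 at the score of 0.25. With only DS 0 passed by edgeR (117 nominal). Without the replicate block, unpaired, 70 passed. Leaving out 1 library gave 59 to 806 calls.

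Bulge-like against other basal had 47 genes differing 4-fold. This was 85 with doublets kept and 85 with clustering on all genes, 90 at resolution 0.5, and 74 with 500 genes and 10 percent. Only 1 library remained with doublets kept, with all genes and at resolution 0.5, so these counts need no agreement between libraries. The edgeR fit had 83 calls, against 16 by DESeq2, 32 without the replicate block (unpaired), 1422 with 500 genes and 10 percent, 133 at resolution 2 and 814 at the score of 0.25.

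Melanocyte-like cells had 270 genes differing 4-fold, and 123 with doublets kept, over 3 libraries. Their edgeR fit had 2024 calls, against 950 by DESeq2, 1262 without the replicate block (unpaired) and 1075 with doublets kept. For immune-like cells edgeR had 1618 calls and DESeq2 789. For 10X against DS the 2261 calls became 896 with 500 genes and 10 percent, and leaving out 1 library gave 792 to 1545. DESeq2 called 11, 6 and 15 interaction genes where edgeR called 1, 2 and 1.

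Gene lists called by camera, 11, 11, 12, 13, 19 and 18 for suprabasal, bulge, inner, differentiated, melanocyte and immune-like cells, became 0, 0, 0, 0, 0 and 0 with an estimated correlation. By fry none of them passed either, and fry called 2, 0, 0, 1, 0 and 0 lists that camera had not called. Both tests are limited by the residual degrees of freedom, 1 for bulge, melanocyte and immune-like cells, where hardly any list could pass. The lost calls therefore do not decide about these lists. Without the replicate block, unpaired, 8 were called for differentiated cells. Leaving out 1 library gave 2 to 13 lists for suprabasal, 4 to 15 for inner and 2 to 16 for differentiated cells. The antimicrobial list of differentiated cells reversed without 10X 2, with adjusted p from 0.00266 to 0.991.

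The 10X minus DS difference in class share changed sign in several alternatives; DS 1 enters as 0 wherever none of its cells was named. It became 1.63 points for basal cells with 500 genes and 10 percent and 2.13 at resolution 2. For suprabasal cells it became 9.91 with 500 genes and 10 percent, 0.0321 at resolution 0.5, 1.21 at resolution 2 and 5.31 with clustering on all genes. It became 0.463 for differentiated cells at resolution 0.5 and 1.52 at the score of 0.25. Inner root sheath cells had 0.678 at resolution 0.5 and 1.43 with all genes, and hair shaft cells 2.35 at resolution 0.5. Cycling cells had -0.653 with doublets kept and -2.20 with all genes. Fibroblast-like or smooth muscle-like cells had -5.46 with doublets kept, where 12 cells of DS 1 were named fibroblast-like.

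Some alternatives could not be run because 1 library remained. These were edgeR for bulge-like cells without either library, with only DS or only 10X, with doublets kept, at resolution 0.5 and with all genes, inner root sheath and shaft at resolution 0.5, and melanocyte and immune-like cells without either library. The replicate block for 10X against DS could not be run, since DS 1 had no named keratinocytes.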

Other observations

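The values of single clusters below were chosen after the data were examined; no tests were made on them, and each comes from 1 suspension unless several libraries are named.

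Bulge-like cells of 10X 1 formed 2 clusters, of 729 and 190 cells. In the second, MGP was at 2235 against 33.1 CPM, ratio 67.6, 95% interval 58.1 to 79.0, TIMP3 at 584 against 48.1 CPM, ratio 12.1, 95% interval 10.5 to 14.0, and HOPX, which marks bulge cells in mouse follicles, at 168 against 25.8 CPM, ratio 6.50, 95% interval 5.24 to 8.09. DKK3 was at 131 against 673 CPM, ratio 0.195, 95% interval 0.167 to 0.226, and VIM at 31.7 against 245 CPM, ratio 0.129, 95% interval 0.0931 to 0.175.

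Metallothionein MT2A was higher in cycling-like cells than in keratinocytes in every library with such cells: 2505 against 669.6 CPM, ratio 3.74, 95% interval 2.67 to 5.15 in DS 2, 2978 against 532 CPM, ratio 5.60, 95% interval 4.61 to 6.79 in DS 3, 2571 against 398 CPM, ratio 6.46, 95% interval 6.28 to 6.64 in 10X 1 and 4095 against 430.4 CPM, ratio 9.51, 95% interval 9.01 to 10.1 in 10X 2.

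Endothelial-like cells of 10X 1 carried MHC class II RNA. HLA-DRA was at 2199 against 10.2 CPM, ratio 217, 95% interval 189 to 249, the invariant chain CD74 at 5632 against 37.5 CPM, and the interferon-induced IFI27 at 3056 against 4.34 CPM, ratio 704, 95% interval 581 to 860.4.

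T cell-like cells had KLRB1 at 882 against 0.415 CPM, ratio 2124, 95% interval 1158 to 4336 in 10X 1. CD69, an early activation and residency marker, was at 3244 against 1.55 CPM, ratio 2097, 95% interval 1528 to 2950.5. In 10X 2 CXCR4 was at 1448 against 5.55 CPM, ratio 261, 95% interval 169 to 419 and CD8A at 185 against 1.55 CPM, ratio 119, 95% interval 46.5 to 343.

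Unnamed clusters were not without character. CST6 was at 7632 against 255 CPM, ratio 29.9, 95% interval 29.2 to 30.7 in a cluster of 244 cells of 10X 1, and at 15592 against 1259.8 CPM in 133 cells of 10X 2. SPINK5 was at 2212 against 231 CPM, ratio 9.58, 95% interval 9.28 to 9.89 and 1950.3 against 113 CPM, ratio 17.3, 95% interval 15.8 to 19.0 in the same clusters. A cluster of 170 cells in 10X 2 had SAA1 at 541 against 8.21 CPM, ratio 65.9, 95% interval 47.4 to 94.3. Another unnamed cluster of 10X 1, with 195 cells, had a median of 849 UMIs.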
